A study of Drosophila melanogaster with 3 samples.

How the data were processed

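Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos collected 0 to 24 hours after egg laying from flies carrying a transgene for Zeste fused to enhanced green fluorescent protein. Per the labels, the fusion protein was pulled down with an antibody against GFP and chromatin was sheared by sonication to fragments of 200 to 800 bp. The labels number 3 biological replicates and give each its own biosample. All 3 belong to 1 group, so no groups of samples were compared. The replicate numbers were taken from the labels. A control experiment named as possible in the labels was not analysed here.

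The deposited files were peak lists on assembly dm6. Per the deposited file lists, each replicate had a list of regions ranked by irreproducible discovery rate (IDR) and a thresholded list, called per sample against a control. The series had 4 further pairs of ranked and thresholded lists made from all 3 libraries, of which 1 thresholded list is called conservative. These series lists were treated as pooled values because they do not say which replicates each compares. The aligner and the peak caller are not given in the sources used here. Column 5 held a score, deposited by the authors, that scales the IDR in whole numbers. Column 7 held the authors' signal value per peak, whose scaling is not given in the sources used here. Column 9 held the authors' −log10 false discovery rate on a log10 scale, and column 10 the summit's offset from the peak start. Column 12 of the ranked lists held the deposited −log10 of the global IDR. A total of 32 further columns in the series ranked lists were not used. Scores and signal values are the authors' own and were used only to describe, rank or filter peaks within a list, apart from the agreement of signal between replicates, which used ranks and log2 values. The files hold no read counts, so the sequencing depth is unknown and intervals on shares cover counting error over peaks only.

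Every thresholded list was checked against the ranked lists. Each held only regions with a global IDR of at most 0.01, and between 74 and 142 regions per list passed that threshold without being listed. The deposited file list names 1 further region file as a parent of the thresholded lists. No row was identical between the thresholded lists of any pair of replicates. Sequences came from the Release 6 reference genome and annotation from Ensembl release 115. All 917864 regions on chromosome arms 2L, 2R, 3L, 3R, 4, X and Y in the 14 lists lay within the reference chromosome lengths. Regions on other scaffolds were left out, which removed 3 conservative peaks. Coordinates are 1-based on dm6.

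Peaks were taken as shared when they overlapped by at least 1 bp, and sharing was compared with 100 draws of the same number of regions from the replicate's own ranked list. A peak was assigned to a promoter when its summit lay within 500 bp of an annotated transcription start site (TSS), and otherwise to 5′ UTR, coding sequence, 3′ UTR, other exon, intron or intergenic sequence, in that order. The background was the 133901 ranked regions of the same series list that failed the IDR threshold and overlapped no thresholded peak. Fisher's exact test was two-sided unless stated otherwise. Motifs were searched on both strands within 100 bp of the summit. Each window was compared by an exact McNemar test with 1 window of the same width 1000 bp away, on a side drawn at random. The Zeste consensus was YGAGYG, where Y is C or T. A panel of 32 consensus motifs, all 2080 6-mers counted with their reverse complements, and 28 gene lists were tested. A gene was counted as bound when a conservative summit lay within 500 bp of 1 of its TSSs, and the gene background was the 10742 protein-coding genes with a ranked region in that window. Where every gene of a list was bound, the odds ratio for the alternatives was computed with 0.5 added to each cell. Benjamini-Hochberg adjustment was applied within each family of tests. Shares carry Wilson intervals at 95% confidence. Correlations with signal were tested with 100000 permutations across peaks, which are not independent replicates. The same correlation within promoter peaks and within other peaks is not reported here. Biological replicates have separate biosamples, and the SD over 3 lists includes differences in list length.

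The motif panel, the gene lists, the designs and most alternatives were fixed before the data were examined. Named genes followed a rule fixed at the same time. It took the protein-coding genes with a TSS nearest to and within 500 bp of the 25 strongest such peaks present in every replicate list. It added up to 4 bound genes with the highest signal from the Zeste target list, the Hox list and each list with an adjusted p under 0.05, and up to 4 unbound members in alphabetical order. Genes outside this rule are also named to describe lists and loci, among them en, Abd-B, Scr, hh, wg, slp1, sls and Cp190. Genes near the left-out regions and genes with many peaks were named after their values were seen. Leaving out a replicate meant keeping the peaks of 1 remaining replicate list that overlap the other, so this alternative also replaces the series list by peaks shared between 2 replicates. Alternatives covered the other series lists, leaving out each replicate, stricter peak sets, other windows, flanks, consensus forms and backgrounds. The planned IDR threshold of 0.01 turned out to be the authors' own.

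The motif, 6-mer, gene-list and overlap steps were tested on simulated data. With the motif planted in some of 2000 random windows, 43.15% of windows were found with it, equal to the simulated share. The planted word ranked 1 among 2080 6-mers, and 0 were called without planting. A gene list with planted binding was called and 0 of 20 random lists were, over 13968 genes. All 300 planted overlaps among 1000 intervals were found. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.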

Results

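Binding of the transcription factor Zeste, a regulator of white and of homeotic genes, was mapped by ChIP-seq against GFP in whole embryos aged 0 to 24 hours that express a Zeste-GFP fusion. The data comprise 3 biological replicates of 1 group. The questions the design allows are where Zeste was bound, how well the replicates match, and how bound regions differ from regions that were ranked but failed the IDR threshold. Sequencing depth is unknown, since the files give peaks and no read counts.

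The conservative list of the series held 3136 peaks, of which 3133 lay on the chromosome arms analysed. The replicate lists held 1569, 2509 and 1734 peaks (1937 ± 502, SD, n = 3), with a median width of 360 to 380 bp. The strongest peak in every replicate lay at mub, with signal values of 3718, 6545 and 3062. Of the peaks of replicate 1, 88.2% overlapped a peak of replicate 2 and 74.9% a peak of replicate 3. For replicate 2 the shares were 55.0% with replicate 1 and 57.1% with replicate 3, and for replicate 3 they were 67.0% with replicate 1 and 81.9% with replicate 2. The mean over these shares was 70.7%. They come from 3 pairs read in both directions, so they are not independent and also reflect list length. Regions drawn from the ranked lists overlapped in at most 3.81% of cases in any of 100 draws per pair, a permutation p of 0.0099 for each pair and the smallest those draws can give. Across conservative peaks, log2 signal correlated between replicates with Spearman's rho of 0.856 for replicates 1 and 2, 0.765 for 1 and 3, and 0.780 for 2 and 3 (Pearson's r 0.944, 0.919 and 0.947). These peaks were kept by an IDR threshold, which favours regions of like rank, so the values describe selected peaks and are not a measure over all regions. Peaks are also not independent replicates. Of the conservative peaks, 1149 (36.7%) were present in every replicate list and 765 (24.4%) in none of them. Presence meant an overlap of at least 1 bp, so a weak peak beside a stronger one can count as present. Of 10 groups by signal, the lowest had 13.4% of its peaks in every list and the next 0.958%. The signal of a replicate was likewise that of its highest overlapping region.

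The strongest promoter peak of the series lay at mub, which encodes a KH-domain RNA-binding protein, on 3L from 21879131 to 21879774, with a signal value of 13283 and its summit 161 bp upstream of the TSS. It was followed by svp, a nuclear receptor gene, with 12123, the Hox gene abd-A with 9066 and the Pax gene eyg with 8289. The zeste gene itself ranked 7 of all conservative peaks, on X from 2447769 to 2448519, with a signal of 8289 and a summit 277 bp downstream of its TSS. Signalling genes in this group were upd2, a JAK/STAT ligand, with 6710, vn, an EGF receptor ligand, with 6292, and dpp, a BMP ligand, with 5328. Developmental regulators of transcription included odd with 6648, eya with 6229, Awh with 6071, Ubx with 6020 and Mef2 with 5003. The other genes were Dys (dystrophin) with 7193, nolo with 6725, lin-28 with 6450, Tollo with 6347, Ntan1 with 6168, Imp with 6072, CG13300 with 5641, CG3097 with 5508, CG2991 with 5415, Lam (a lamin) with 5210, CG13917 with 4661 and Toll-7 with 4578. All 25 were present in every replicate list by the rule that chose them. The summit lay upstream of the TSS at 22 of them, the exceptions being z, odd and dpp, and 24 had the Zeste consensus within 100 bp of the summit, the exception being z. At upd2 that window held 12 consensus sites, at Imp 8 and at Dys 7.

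Zeste peaks were concentrated at promoters. A TSS lay within 500 bp of the summit for 45.5% of conservative peaks (95% Wilson interval 43.7 to 47.2, 1425 of 3133), against 14.4% of ranked regions that failed. In the replicate lists the share was 47.8% ± 2.07 (SD, n = 3). Random positions gave 13.4%, so failed regions lay near TSSs little more often than random sequence. Open chromatin was not measured, so its part in the promoter share is unknown. Coding sequence held 2.20% of summits against 20.3% of failed regions, introns 33.9% against 37.9%, intergenic sequence 15% against 22.7% and 3′ UTRs 0.989% against 2.94%. The 5′ UTR share was 1.53% against 0.958%. The odds ratio for promoters was 4.97, and the one-sided Fisher's exact p had a log10 of −368. Adjusted p-values from Fisher's exact test were 3.1e-203 for coding sequence, 6.3e-06 for introns, 7.2e-26 for intergenic sequence, 3.7e-13 for 3′ UTRs and 0.0026 for 5′ UTRs. Other exons, at 0.862% and 0.855%, did not differ detectably (Fisher's exact test, adjusted p = 0.922). The median promoter summit lay 51 bp upstream of the TSS, at −51 bp with quartiles of −148 and 43 bp, and 64.0% of promoter summits lay upstream. The median was −89, −77 and −60 bp in replicates 1, 2 and 3, and −92 to −78 bp with 1 replicate left out.

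**Figure D1:**
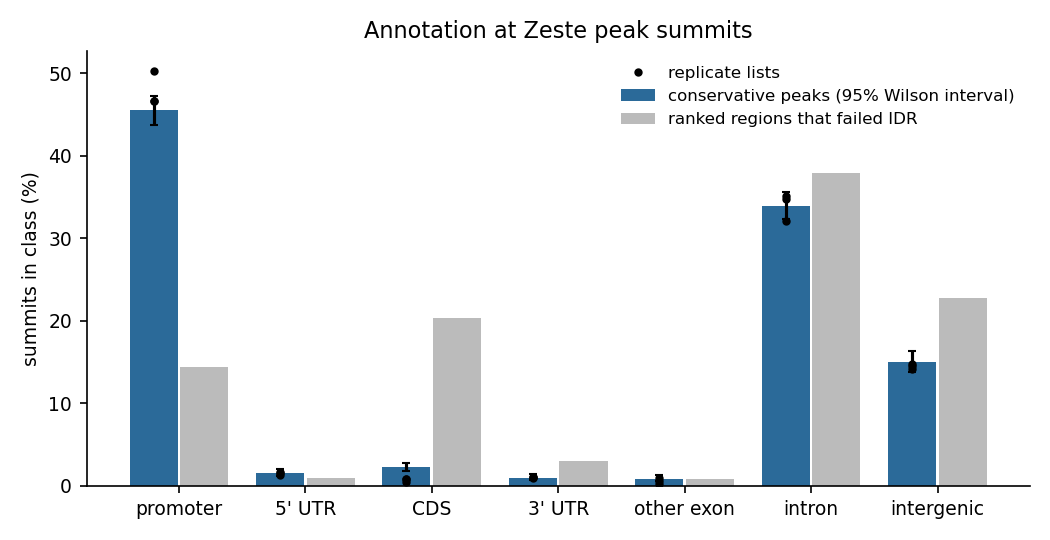
Share of summits in each annotation class (vertical axis, percent) for 3133 conservative peaks (blue, with 95% Wilson intervals), failed ranked regions (grey) and the 3 replicate lists (black points). Promoters hold 45.5% of conservative summits and 14.4% of failed regions.

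The X chromosome carried fewer peaks per Mb than 2L, 2R, 3L and 3R. It held 18.1 conservative peaks per Mb, against 25.5 on 2L, 25.3 on 2R, 25.3 on 3L and 23.1 on 3R. Chromosome 4 held 10.4 per Mb and the Y chromosome 0.545. Failed ranked regions were also sparse there, at 113 per Mb on chromosome 4 and 104 on the Y, against 942 to 1048 on the other arms. The low peak density on chromosome 4 is therefore not a depletion against that background. The Y, with 2 peaks, was low against its failed regions as well. Neither was tested. In the replicate lists the X held 11.5 ± 2.92 peaks per Mb and 3R held 14.0 ± 3.99 (SD, n = 3). The X carried 13.6% of peaks on X, 2L, 2R, 3L and 3R together against 18.4% of failed regions on those arms, an odds ratio of 0.700 (two-sided Fisher's exact test, p = 1.9e-12). The sex of the embryos is not given in the labels.

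The Zeste consensus YGAGYG marked most peaks. It occurred within 100 bp of the summit at 64.3% of conservative peaks (95% Wilson interval 62.7 to 66.0, 2016 of 3133), against 28.0% of flanking windows. The odds ratio was 4.73 (exact McNemar test, p = 6.9e-177), and 6.99 to 9.90 with 1 replicate left out and 10.2 for peaks in every replicate list. The flanks on both sides held it in 28.2% of windows, and failed ranked regions in 29.8%. In the replicate lists the share was 71.1% ± 1.92 at peaks and 28.3% ± 1.08 in flanks (SD, n = 3). Against failed regions matched on GC content and promoter class, which held it in 30.5%, the odds ratio was 4.12 by Fisher's exact test (p = 1.4e-161). YGAGYG had the highest ratio of peaks to flanks, 2.30, among the 60 distinct orderings of its letters, and the next ordering had 2.00. Sites were densest around the summit, at 8.95 per kb in the 20 bp bin centred at −10 bp, compared with 2.01 per kb in the bin centred at −990 bp.

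**Figure D2:**
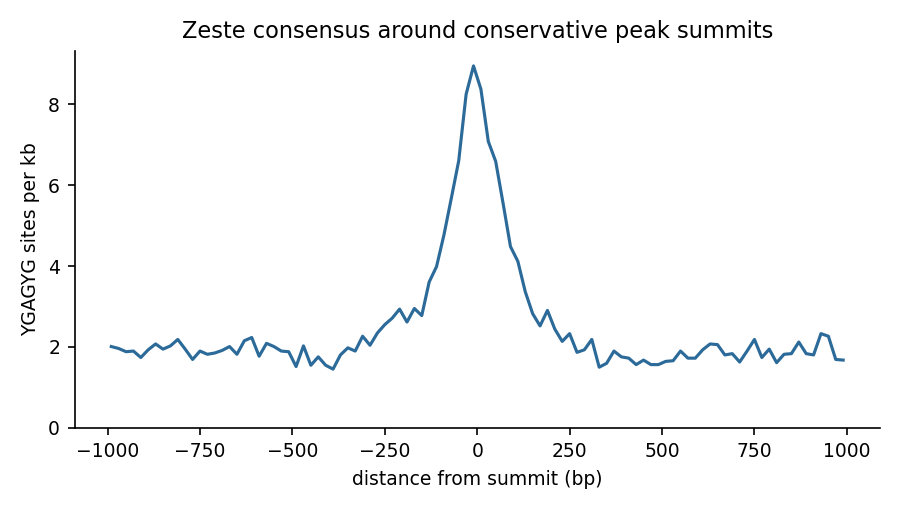
Density of YGAGYG sites (vertical axis, sites per kb, 20 bp bins) by distance from the summit (horizontal axis, bp) over the conservative peaks. The density reaches 8.95 per kb at the summit and falls to about 2.01 per kb at −990 bp.

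Stronger peaks carried the consensus more often. When peaks were divided by signal into 10 groups of like size, 41.4% of the lowest group (130 of 314) and 95.2% of the highest (299 of 314) had it. The median signal was 99.3 for the 1117 peaks with 0 sites, 115.2 with 1, 145 with 2, 233 with 3 and 429 for the 253 peaks with 4 or more. The number of sites correlated with log2 signal across peaks with Spearman's rho of 0.395 and Pearson's r of 0.439 (permutation p = 1e-05 for both, the smallest that 100000 resamples can give). Peaks found in every replicate list had the consensus in 79.5% of cases, and peaks found in none of them in 48.1%.

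**Figure D3:**
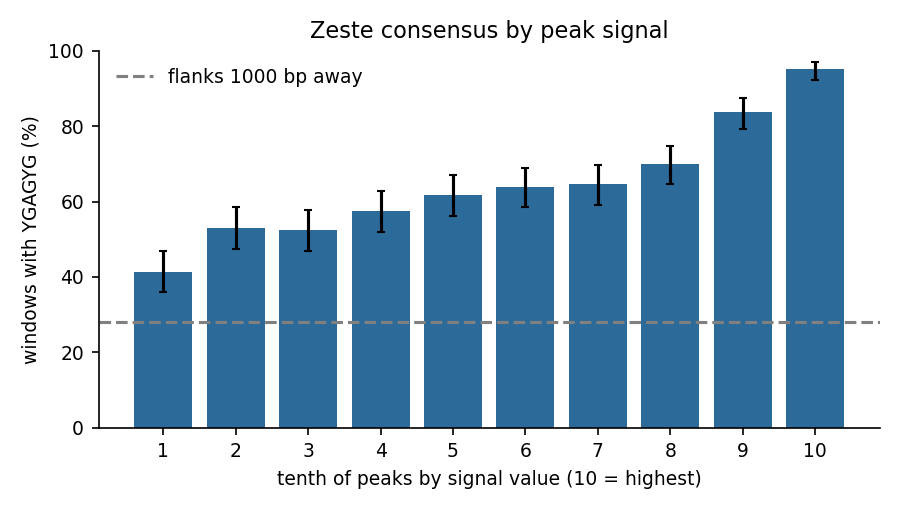
Share of windows with YGAGYG (vertical axis, percent, bars with 95% Wilson intervals) by group of conservative peaks in order of signal (horizontal axis, 10 is the highest). The share is 41.4% in the lowest group and 95.2% in the highest, and the dashed line marks the 28.0% of flanking windows.

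Among other motifs, the GAGAG element of GAGA factor was the most enriched, in 48.2% of peaks against 24.0% of flanks (odds ratio 3.21, exact McNemar test, adjusted p = 1.6e-91). A GTGTGT repeat occurred in 26.3% against 15% (odds ratio 2.09, exact test, adjusted p = 1.9e-28), and the AP-1 site TGASTCA in 4.12% against 1.92% (odds ratio 2.19, adjusted p = 1.7e-06). The AP-1 site can read TGAGTCA, which shares TGAGT with the Zeste word TGAGTG. In peaks without YGAGYG it occurred in 3.13% against 1.88% and did not pass (exact McNemar test, adjusted p = 0.347). Over all peaks the initiator TCAGTY rose from 18.4% to 23.2% (exact test, adjusted p = 1.2e-05), which was not separated from closeness to a TSS. Including the Zeste consensus, 8 of the 32 motifs were enriched, and 5 without replicate 3. The remaining 3, CAGCTG, the Sp1/KLF motif and CRWYG, were not enriched against matched failed regions. That comparison called 6 motifs, among them the Dsp1 word GAAAA, in 65.0% against 57.6% (odds ratio 1.36, Fisher's exact test, adjusted p = 1.2e-08), which did not pass against flanks. Homeodomain sites TAATTA were rarer at peaks, in 7.09% against 12.7% (odds ratio 0.524, exact test, adjusted p = 1.0e-12). Against matched failed regions, at 8.94%, the odds ratio was 0.777 (Fisher's exact test, adjusted p = 0.0231). Also rarer than in flanks were the Bicoid site TAATCC, in 3.29% against 6.42%, and the CCAAT box, in 28.3% against 34.7%. The Pleiohomeotic core GCCAT did not differ detectably from flanks, at 31.5% against 33.3% (exact McNemar test, adjusted p = 0.204), and was rarer than in matched failed regions, at 38.7% (odds ratio 0.729, Fisher's exact test, adjusted p = 1.2e-08). Of all 6-mers, 418 were enriched and 556 depleted. The first was CACTCA, the reverse complement of TGAGTG, in 38.7% of peaks against 10.6% of flanks.

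In the 1117 peaks without YGAGYG, the GAGAG element was the single enriched panel motif. It occurred in 37.7% against 24.0% of flanks (odds ratio 1.97, exact McNemar test, adjusted p = 2.0e-11). The enriched 6-mers with the lowest p there were GAGAGC, in 19.3% against 9.85%, and AGAGAG, in 20.5% against 11.2%. In total 51 6-mers were enriched in these peaks.

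Several groups of developmental regulators were bound more often than other genes. A conservative summit lay at a promoter of 1245 of 10742 background genes (11.6%). All 8 classical Zeste-linked genes in the background were bound (Fisher's exact test, adjusted p = 2.2e-07), of which 5 were in every replicate list and en, with a signal of 71.5, in 0. With 0.5 added to each cell the odds ratio was 130.5, and with 1 replicate left out it was 26.3 to 34.0. With the series list of 2476 peaks it was 16.9. After z, Ubx and dpp, the highest signal was at white (w), the eye pigment transporter gene, on X from 2796417 to 2796739, with 943 and rank 242. Hsp70Aa was not in the background and had no conservative summit within 500 bp of a TSS. Of the 8 Hox genes, 6 were bound (odds ratio 23.0, Fisher's exact test, adjusted p = 2.2e-04), 3 of them in every replicate list, with Antp at 366 and Dfd at 83.9 after abd-A and Ubx, and lab and pb were not. With 1 replicate left out the Hox odds ratio was 9.43 to 12.2 (Fisher's exact test, adjusted p = 0.0195 to 0.0355). Developmental genes classically bound by Polycomb had 38 of 68 bound (55.9%, odds ratio 9.93, exact test, adjusted p = 2.5e-17), led by eyg, eya, mid with 4072 and bi with 2427. Unbound members included C15, Dr, Gsc and Six4. Leaving out 1 replicate gave an odds ratio of 5.84 to 8.26. Segmentation genes had 11 of 19 bound (odds ratio 10.6, exact test, adjusted p = 8.5e-06), led by odd, kni with 3817, Kr with 3354 and knrl with 3348. Unbound members included eve, ftz, gsb and gt. The odds ratio was 5.91 with the series list of 2476 peaks. Signalling genes had 17 of 31 bound (odds ratio 9.38, exact test, adjusted p = 5.6e-08), led by vn, dpp, spi with 4005 and htl with 3262. Unbound members included Mad, Med, Stat92E and Wnt5. The odds ratio was 6.05 with the series list of 4457 peaks and 18.2 when the whole gene body was searched. These lists share bound genes, so their tests are not independent. Ubx, Antp, Scr and Abd-B are in both the Hox and the Zeste-linked list, and en, hh, wg and slp1 in both the Polycomb and the segmentation list. The signalling list also holds hh, wg and dpp, and the Zeste-linked list also holds dpp and en.

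Further lists were also bound above the background. Trithorax group genes had 9 of 20 bound (odds ratio 6.28, Fisher's exact test, adjusted p = 5.2e-04), led by psq with 1301, skd with 366, Trl with 294 and lolal with 284, while Bap111, Bap55, Bap60 and Bre1 had no conservative summit within 500 bp of a TSS. The odds ratio was 9.31 to 11.0 with 1 replicate left out and 12.6 at an IDR of at most 0.001, a setting chosen after the data were seen. Muscle genes had 9 of 19 bound (odds ratio 6.91, Fisher's exact test, adjusted p = 3.6e-04), led by Mef2, Zasp52 with 546, sns with 398 and Mlp84B with 208, while Act87E, Mhc, Mlc1 and Mlc2 had no conservative summit within 500 bp of a TSS. One bound member of the trithorax list, sls, encodes a giant muscle protein and is also in the muscle list. The muscle call was lost without replicate 3 (odds ratio 4.59, exact test, adjusted p = 0.0571) and among genes with the same number of TSSs (permutation, adjusted p = 0.103). E(spl) and Notch pathway genes had 9 of 18 bound (odds ratio 7.68, exact test, adjusted p = 2.3e-04), led by numb with 978, mam with 489, E(spl)m2-BFM with 225 and neur with 161, while E(spl)m4-BFM, E(spl)m5-HLH, E(spl)m8-HLH and E(spl)mdelta-HLH had no conservative summit within 500 bp of a TSS. By the same exact test that call was lost without replicate 2 (odds ratio 2.53, adjusted p = 0.414), without replicate 3 (odds ratio 2.14, adjusted p = 0.394), with the peaks at or above the median signal (odds ratio 4.09, adjusted p = 0.0538) and with peaks in every replicate list (odds ratio 2.59, adjusted p = 0.402).

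Cytosolic ribosomal protein genes had 33 of 80 bound in the conservative list (41.3%, odds ratio 5.47, Fisher's exact test, adjusted p = 1.7e-10), led by RpS28a with 747, RpS27 with 191, RpL7 with 168 and RpL7-like with 155. Unbound members included RpL10, RpL10Aa, RpL10Ab and RpL11. The direction turned in every set that requires a peak in replicate 1. The odds ratio was 0.787 for peaks shared by replicates 1 and 3, 0.900 for those shared by 1 and 2 and 0.804 for peaks in every replicate list, with an adjusted p of 1 by Fisher's exact test in each. It was 2.80 for peaks shared by replicates 2 and 3 (Fisher's exact test, adjusted p = 0.0111). The replicate lists held 4, 18 and 19 of these genes.

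Chemoreceptor genes, few of which embryos use, had 1 of 122 bound, Gr93a (odds ratio 0.0623, Fisher's exact test, adjusted p = 4.9e-05), and cuticle protein genes 1 of 82, Cpr73D (odds ratio 0.0934, Fisher's exact test, adjusted p = 0.0020). Unbound members included Gr10a, Gr10b, Gr21a and Gr22a in the former and Acp65Aa, Ccp84Aa, Ccp84Ab and Ccp84Ac in the latter. Without replicate 3 the odds ratio for chemoreceptors was 0.140 (Fisher's exact test, adjusted p = 0.0525). For cuticle genes the adjusted p of the same test was 0.0853 without replicate 2, 0.0645 without replicate 3 and 0.0851 with peaks in every replicate list, each with an odds ratio of 0. No difference passed the test for the other 17 lists. Polycomb group genes had 4 of 12 bound (Fisher's exact test, adjusted p = 0.0967), heat shock genes 3 of 17, neuronal markers 2 of 16, glial markers 3 of 10, germ line markers 0 of 10 and proteasome genes 1 of 37. Insulator protein genes had 3 of 9 bound, tracheal and epidermal markers 3 of 9, gut, fat body and blood markers 2 of 10, and cell cycle regulators 4 of 27, of which psq entered that list through a synonym. Mitochondrial ribosomal protein genes had 6 of 54 bound, translation factor genes 5 of 42, respiratory chain genes 2 of 57, and general transcription factor and Mediator genes 1 of 40. Seminal protein genes had 0 of 26 bound, histone genes 0 of 3, and the eggshell list 1 of 11, Cp190, which was caught by its name and encodes an insulator protein.

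**Figure D4:**
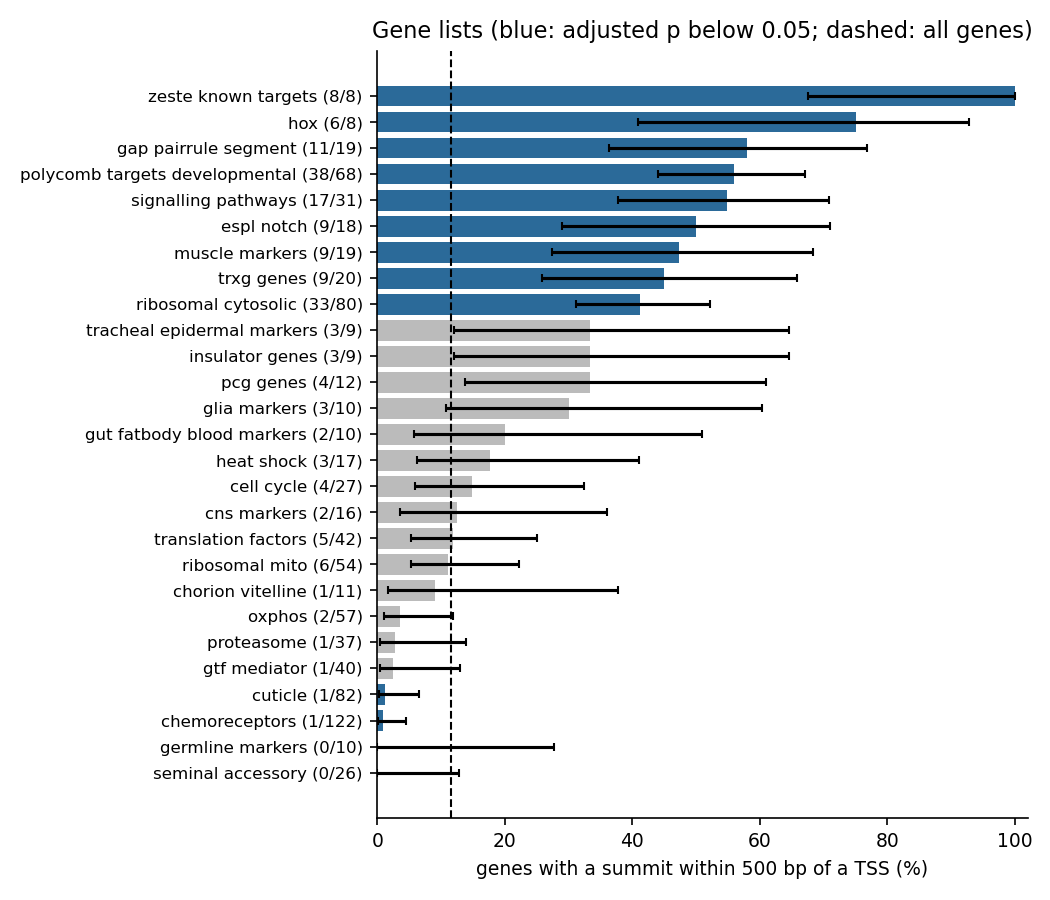
Share of genes with a conservative summit within 500 bp of a TSS (horizontal axis, percent, bars with 95% Wilson intervals) for the gene lists with at least 8 background genes, with bound and background counts beside each name. Blue bars have an adjusted p under 0.05, and the dashed line marks the 11.6% of all background genes.

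The bithorax complex, which holds the Hox genes Ubx, abd-A and Abd-B, was densely bound. From the end of Ubx to the start of Abd-B, on 3R from 16656623 to 16972236, it held 34 peaks in 316 kb, or 108 per Mb, against 23.1 per Mb for 3R. Of these peaks, 14 were in every replicate list, 23 had the Zeste consensus and 4 lay at promoters. The strongest were at the abd-A promoter with 9066 and the Ubx promoter with 6020, both with summits upstream of the TSS. A summit at 16812080, 10781 bp from the nearest TSS, had 2140, and a summit at 16764223, nearest to the noncoding RNA gene bxd, had 1607. The Abd-B promoter peak, with its summit at 16972285 just beyond this interval and not among the 34, had 71.9 and was in 1 replicate list. The Antennapedia complex from lab to Antp held 9 peaks in 338 kb, of which 2 were in every replicate list. The Antp promoter peak, with its summit at 6999536 just beyond that interval and not among the 9, had 366 and was in every replicate list. The density of these loci was not tested.

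**Figure D5:**
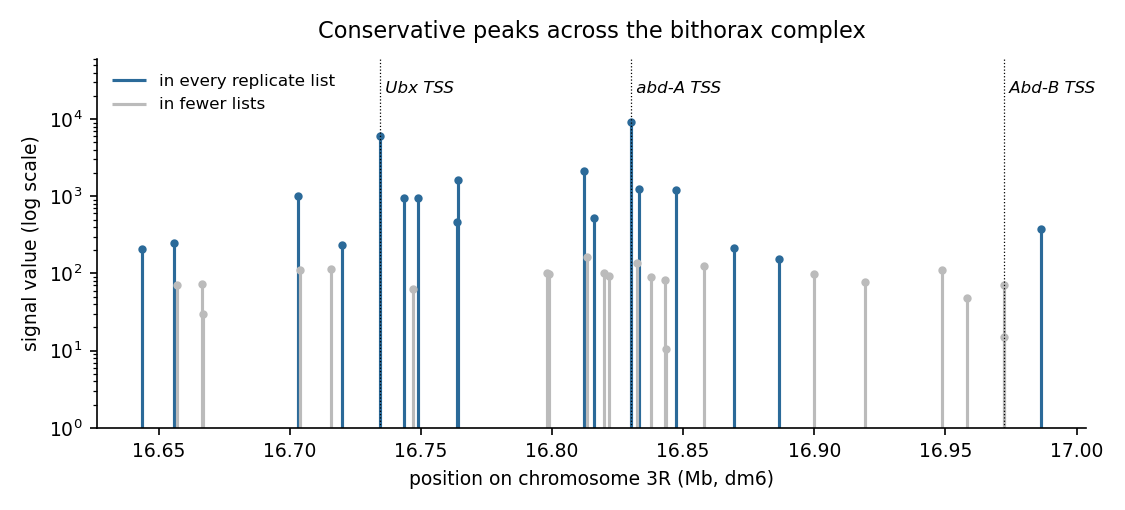
Conservative peaks across the bithorax complex and 20 kb to each side, by summit position (horizontal axis, Mb on 3R) and signal (vertical axis, log scale), with peaks in every replicate list in blue and others in grey. Dotted lines mark TSSs, and the highest peaks lie at abd-A with 9066 and Ubx with 6020.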

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

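The tests of soft-masked sequence and of consensus sites in the called peak at z were set before their results were seen. The other tests in this part were chosen only after the result was seen.

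The comparisons above did not use regions that passed the IDR threshold but stand outside the conservative list, some of them with a strong signal. There were 125 such regions, 122 of them on the chromosome arms analysed. The strongest, 176 bp from a TSS of chic, the profilin gene, on 2L from 5979849 to 5980859, had a signal of 12268 and would rank 2 among the conservative peaks. Others lay nearest to COX7AL2 with 3284 and crp with 2300, named for their signal after it was seen. Of the 122 regions, 72 lay on 3R and 35 on 2L, in 51 clusters when joined within 20000 bp, and the largest cluster held 13 regions.

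Repeated sequence is argued against as the source, since 1.64% of their windows were mostly soft-masked in the reference, against 1.88% for the conservative peaks. Background without Zeste sequence is also argued against, since 59.0% had the Zeste consensus (95% Wilson interval 50.1 to 67.3), against 29.8% of failed regions (Fisher's exact test, p = 2.6e-11). That interval and test count the 122 regions as independent although they lie in 51 clusters, so both overstate the precision. Conservative peaks of like signal gave 66.5%. The further region file named as a parent of the lists may be an exclusion list, in which case these regions were removed on purpose. This was not tested, and no biological explanation was tested because the design has 1 group.

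The binding at cytosolic ribosomal protein genes was present in some replicates more than in others. Even at equal list sizes of 1567 peaks, replicate 1 had 4 such genes and the others 11 and 18 (odds ratio 0.310). Other lists of like length kept the higher share. The odds ratio was 2.29 for the 1567 peaks at or above the median signal (Fisher's exact test, adjusted p = 0.0449). It was 2.80 for the 1430 peaks shared by replicates 2 and 3. Both lists draw on the libraries that carry the higher share, and the comparison at equal sizes sets 1 library against others that share genes. Whether the shorter list of replicate 1 was the whole cause therefore cannot be told. Replicate 2 fell from 18 genes to 11 at the equal size, so list length may contribute. Why replicate 1 differs cannot be told from 1 library. Of the genes of 4 other housekeeping lists, 7.37% were bound (95% Wilson interval 4.44 to 12). A property of housekeeping promoters in general is argued against only as far as these lists stand for them. They were not matched to the ribosomal protein genes on transcription, which was not measured here, so a signal from highly active promoters stays open. The consensus occurred at 42.4% of the ribosomal protein peaks (14 of 33, 95% Wilson interval 27.2 to 59.2). Other promoter peaks, weighted to the same signal groups, gave 60.7%. Fisher's exact test gave an odds ratio of 0.400 (p = 0.010), but against other promoter peaks of those groups without the weighting. Recruitment through the consensus as often as at promoter peaks of like signal is argued against, while 14 of these peaks did hold it. A difference between replicate libraries that acts on these promoters remains open and may be technical or biological.

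The peak at z ranks 7 without a consensus site within 100 bp of its summit. Ranked regions within 40 kb of it had a median signal 1.58 times that of other X regions, and 0 of 281 other windows on the X had a median as high. Additional copies of the z region in the transgenic flies would raise this median, so a contribution of copy number stays open. The gene boi, whose span includes the z summit, held 9 conservative peaks in 25.9 kb. Such a group of peaks could also raise the median, which was not tested. The peak stood 63.8 times above the median promoter peak, a ratio taken over called peaks and not over ranked regions. A few added copies could not give such a ratio whatever the neighbouring regions showed. The comparison therefore adds nothing on copy number as the whole cause. The called peak held 3 consensus sites, at −242, −206 and 215 bp from the summit, against 1.39 from the density in failed regions (Poisson exact p = 0.165), which leaves a contribution of outer sites open. No biological explanation was tested.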

How the results depend on the processing

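Stricter IDR, removal of weaker neighbours within 500 bp, return of the left-out regions, matching genes on TSS number, and the alternatives for annotation classes, permuted consensus, motif panel under other lists and TSS distance without a replicate were chosen after seeing the data. No paired analysis was possible because there is 1 group of samples. The promoter share, the X depletion, the Zeste consensus and its relation to signal kept their direction and their side of the threshold under every alternative run. The promoter share ranged from 37.0% with TSSs within 250 bp to 57.7% within 1000 bp, and the consensus share from 38.7% for TGAGTG to 82.5% with windows of 250 bp to each side. Leaving out replicates gave 1174 to 1430 peaks, a signal agreement of 0.765 to 0.856, 5 to 8 enriched panel motifs and a median TSS distance of −92 to −78 bp. Fewer peaks follow from requiring a peak in both remaining lists, and the cause of the other shifts was not tested. An IDR of at most 0.001 gave 1513 peaks, and peaks in every replicate list gave an agreement of 0.930. The ribosomal protein list turned direction, with odds ratios of 0.787 to 2.80 without replicates and 0.804 with peaks in every replicate list, and the cause is weighed above. Over all gene lists called, 142 values under alternatives kept their call, 9 lost it in the same direction and 3 turned direction. Matching genes on TSS number was counted apart, and with it the muscle list lost its call. Depth is unknown, and its limit on weak peaks could not be measured.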

Other observations

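The motif panel was run on promoter peaks and on other peaks apart. At the 1425 promoter peaks the core promoter element GGTCACACT occurred in 1.12% against 0.140% of flanks (odds ratio 8.0, exact McNemar test, adjusted p = 0.0052), and the initiator in 29.1% against 18.7% (adjusted p = 8.9e-10). These peaks were chosen for lying near a TSS and the flanks lie 1000 bp away, so such a rise is not specific to Zeste. For all peaks against failed regions matched on GC and promoter class, GGTCACACT did not pass (odds ratio 1.91, Fisher's exact test, adjusted p = 0.228). The initiator did (odds ratio 1.32, Fisher's exact test, adjusted p = 2.6e-05). That match used a TSS within 500 bp and not the distance to it. A TSS lay within 250 bp for 37.0% of peaks and 7.91% of all failed regions. The rise of the initiator is therefore not separated from closeness to a TSS. At the 1708 other peaks the CTCF core occurred in 1.70% against 0.527% (29 and 9 windows, odds ratio 3.22, exact McNemar test, adjusted p = 0.0056), and the initiator in 18.3% against 19.5% (adjusted p = 0.508). The CTCF core went the other way at promoter peaks, in 0.351% against 0.632%. Over all peaks it was not enriched, at 1.09% against 0.830% (exact McNemar test, adjusted p = 0.488). The difference between promoter and other peaks was not tested.

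Some gene bodies held many peaks, named here after their counts were seen. The Notch coactivator gene mam held 22 in 69.2 kb, the nuclear receptor gene Eip75B 15 in 113.7 kb and the kinase gene Raf 12 in 48.4 kb. CG1677, sbb and the trithorax group gene tna held 11 each, and bun, ftz-f1, gish and psq 10 each. The counts were not tested and are not adjusted for gene length. The E(spl) complex held 10 peaks in 43.4 kb, of which 9 had the Zeste consensus and 1 was in every replicate list.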
